A study of Mus musculus with 6 samples.

How the data were processed

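The data were 6 libraries of droplet single-cell RNA sequencing (10x Genomics 5' HT v2 kit) from whole mouse skin without hypodermis, 1 for each of 3 groups (wild type, enhancer deletion without alopecia, enhancer deletion with alopecia) in each of 2 sorts of live cells (CD45-positive and CD45-negative). Groups were read from the sample titles. Per the file headers and the submitters' processing notes, the deposited values are raw UMI counts per gene and cell from Cell Ranger 7.1.0 with build mm10, in the barcodes that program called as cells. They were checked to be whole numbers over 32285 genes, the same in all 6 libraries. The annotation release behind the counts was not given in the sources used here. Of the gene identifiers, 32158 (99.61%) were found in GENCODE vM21, from which coordinates were taken.

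Cells were kept with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs. Doublets were scored by simulated doublets, and because the automatic threshold marked few cells per library, the highest scores were removed at a fixed rate of 0.4% per 1000 barcodes of the library. The cell filter removed 3.21%, 1.86% and 4.20% of the wild-type, no-alopecia and alopecia CD45-positive barcodes and 26.7%, 7.56% and 30.4% of the CD45-negative ones. Doublet removal then took 2.68%, 1.34%, 3.85%, 1.82%, 6.70% and 2.84% in the same order. Kept cells had median depths of 4544, 4827 and 4083 UMIs in the CD45-positive and 5007, 5444 and 5658 in the CD45-negative libraries.

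The 3 libraries of a sort were clustered together without batch correction, on counts scaled to 10000 per cell and log-transformed, with 2000 variable genes (Il2ra left out), 30 principal components, 15 neighbours and Leiden resolution 1.0 with seed 0. T and NK cells were clustered again by themselves. Clusters were named by hand from scores and leading genes, with marker genes of 40 classes fixed before the data were examined. Clusters with tied, mixed or low scores or few UMIs, or led by markers of another class or by long genes, stayed unnamed. CD45-negative clusters 2, 6, 13, 18, 19 and 20 and lymphoid clusters 13 and 16 were named by score, though none of their own markers was among their 10 leading genes. CD45-negative cluster 22, the shallowest of its sort (median 888.5 UMIs), was named suprabasal from its leading genes, though its best score was for erythroid cells. Hemoglobin and immunoglobulin genes were left out of that check of leading genes, a choice made after hemoglobin genes were seen to lead a cluster joined into the CD4 T class. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.

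Shares are percent of kept cells of a library. Levels are sums of UMIs over the cells of a class and library, scaled to an equal total (CPM). Ratios were taken between class sums, in classes of at least 100 cells in both libraries, and no p-value was computed, since cells of 1 library are not replicates. A sum of 0 was set to a floor of 3 counts. Gene lists, 27 in number and written before the data were examined, were summarised by the median log2 ratio of members with a summed count of at least 20, where at least 5 members had it. Each median was placed among 10000 random lists matched in 20 expression bins and was given an interval from 1000 Poisson draws. A member counts as higher or lower at 1.5-fold. Of 819 medians computed, 112 were chosen for reporting after all had been seen, and lists that define a class by its own genes were left out. The median log2 ratio of all genes lay from -0.12 to 0.11 over classes and comparisons.

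Single genes were named by a rule fixed before the data were examined. In the 4 classes per sort with most cells in the smaller library, genes with a summed count of at least 50 and at least 50 CPM in the higher library were ranked by the interval bound nearer to 1. Up to 4 genes each way are given for alopecia against no alopecia and up to 2 for the other comparisons. Mitochondrial, ribosomal-protein, hemoglobin, immunoglobulin, T-cell receptor, sex-linked marker and unnamed genes were left out. Genes under 5% of their CPM in another class of at least 20 cells of the same library were skipped, since free RNA can carry them. Il2ra, Ptprc, Ifng, Il15, Cxcl9, Cxcl10, Gzmb and Foxp3 were always examined, and members of lists are named as examples. Some genes that the rule selects are not reported here, and none was put in their place. For shares of cells with an Il2ra UMI, each cell was thinned at random to 1000 UMIs and shallower cells were left out.

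Alternatives fixed before the data were examined were no cell filter, at most 5% mitochondrial UMIs, no doublet removal, 0.8% of doublets per 1000 barcodes, Leiden resolution 2.0, Leiden seed 1, classes from marker UMIs of each cell (also after thinning), trimmed-mean scaling, scaling without mitochondrial and ribosomal-protein genes, and a mean over cells of counts per 10000. For lists they were members with at least 100 counts and members that free RNA cannot carry, and for Il2ra no thinning, thinning to 2000 UMIs, and cells with a Foxp3 and a Cd3 UMI. Added after the data were seen were shares among leukocyte classes, shares of hair shaft cells among follicle keratinocytes or outside keratinocytes, and myeloid classes without cells holding 3 or more UMIs of T-cell receptor complex genes. The ratios were tested on simulated data with 200 changed genes. In regulatory T cells the interval covered the truth for 96.0% of unchanged genes, and 64.2%, 86.6% and 97.0% of genes changed by 1.5-fold, 2-fold and 4-fold had intervals away from no change. In fibroblasts these were 95.7%, 80.6%, 95.5% and 100%. Receptor sequences, chromatin data and any tissue other than skin were not used here.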

Results

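Single-cell RNA sequencing was done on whole skin, freed of its hypodermis, from female mice of 17 to 18 weeks. The mice were wild type, or carried a deletion of an enhancer upstream of Il2ra and either had lost hair (alopecia) or had not. Live cells of each group were sorted into a CD45-positive part, which holds leukocytes, and a CD45-negative part, which holds keratinocytes and stroma. This gave 6 libraries, 1 per group and sort, and the number of mice behind each was not given in the sources used here. The wild-type, no-alopecia and alopecia CD45-positive libraries held 6702, 3340 and 9610 barcodes with 38407339, 20116378 and 50057357 UMIs. In the same order, the CD45-negative libraries held 4575, 16751 and 7123 barcodes with 25735064, 116334373 and 41014981 UMIs. After filtering, 6313, 3234 and 8852 CD45-positive and 3293, 14447 and 4817 CD45-negative cells were left. With 1 library per group, no difference below has a replicate check, and every interval (95%, exact Poisson, Clopper-Pearson or conditional binomial, and Poisson resampling for lists) covers counting error only. Cell classes were named by marker genes, so that each is a class of cells like the named type.

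Il2ra, which encodes the alpha chain of the IL-2 receptor, was lower in both CD45-positive deletion libraries than in wild type. Its level was 239 (234 to 245) CPM (UMIs of the gene scaled to an equal total of all UMIs) in wild type, 150 (144 to 155) without alopecia and 134 (130 to 137) with alopecia. Regulatory T cells, which depend on IL-2, had 939 (897 to 983) CPM in wild type against 387 without and 389 with alopecia. These are log2 ratios to wild type of -1.28 (-1.46 to -1.10) and -1.27 (-1.38 to -1.16), and the deletion libraries differed from each other by 0.01 (-0.18 to 0.19). Dermal gamma delta T cells, the other class rich in Il2ra, had 801 CPM in wild type, 721 without alopecia and 488 with it. Their log2 ratio to wild type was -0.15 (-0.25 to -0.05) without alopecia and -0.72 (-0.80 to -0.64) with it, but the make-up of the class differed too: lymphoid cluster 4 held 24% of it in wild type, 27.7% without and 49.8% with alopecia. In innate lymphoid cells Il2ra was at 318, 184 and 246 CPM in the same order, in CD4 T cells at 93, 63.4 and 51.2 CPM. It was lower in myeloid classes too, at 218, 102 and 71.6 CPM in Langerhans cells, 226, 106 and 82.1 in macrophages and 241, 120 and 113 in type 2 dendritic cells. With alopecia against wild type their log2 ratios were -1.61 (-1.84 to -1.38), -1.46 (-1.69 to -1.23) and -1.09 (-1.28 to -0.91). Many of these cells held 3 or more UMIs of T-cell receptor complex genes. In the same order of groups they were 68.5%, 63.8% and 53.9% of Langerhans cells, 68.2%, 53.8% and 45.0% of macrophages and 69.5%, 61.4% and 62.8% of dendritic cells. Whether T-cell RNA carries the Il2ra of Langerhans cells and macrophages was not tested. The deletion removes a regulatory element and not the transcribed gene (Il2ra, ENSMUSG00000026770, GRCm38 chromosome 2, 11642807 to 11693193, plus strand, GENCODE vM21), so this level checks the genotype labels only in part.

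When every cell was thinned to 1000 UMIs, an Il2ra UMI was found in 47.8% (43.4 to 52.2) of wild-type regulatory T cells, 24.5% (19 to 30.8) of those without alopecia and 26.8% (23.6 to 30.1) of those with it. Their median depths before thinning were 3352, 3350 and 3021 UMIs. Fibroblasts of the same libraries, which should lack the gene, had median depths of 3986.5, 3400 and 2990 UMIs and shares of 0.0% (up to 4.35), 0.433% (0.0110 to 2.39) and 0.0% (up to 2.68). Ptprc, the gene of CD45, was at 791, 657 and 721 CPM in the CD45-positive libraries and at 1.06, 0.0685 and 0.190 CPM in the CD45-negative ones (wild type, no alopecia, alopecia). The sort therefore separated Ptprc in all 3 groups. Ifng and Gzmb had no UMI in any CD45-negative library, which allows up to 0.112%, 0.0255% and 0.0766% of cells with a UMI of each. In the CD45-positive libraries, in the same order, Ifng was at 131, 62.8 and 71.4 CPM, Gzmb at 142, 56.5 and 60.2, Cxcl10 at 102, 69.6 and 37.1 and Cxcl9 at 6.35, 5.02 and 2.77. Foxp3 was at 55.1, 50.7 and 50.9 CPM and Il15 at 14.2, 14.6 and 17.7. In the CD45-negative libraries Cxcl10 was at 30.8, 28 and 24.2 CPM, Cxcl9 at 0.676, 2.45 and 1.69, Il15 at 11.9, 7.31 and 10.9, and Foxp3 at 1.31, 0.665 and 0.789.

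**Figure D1:**
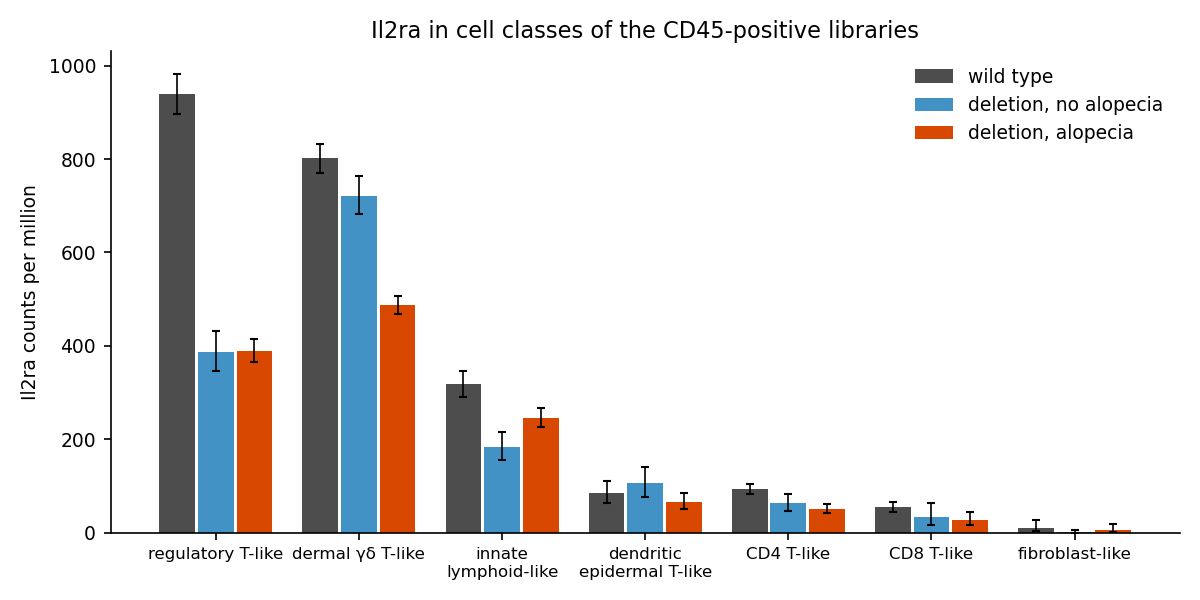
Il2ra in CPM of the summed UMIs of each cell class (y axis, linear from 0), for wild type, deletion without alopecia and deletion with alopecia, in the CD45-positive libraries. Bars are 1 library each and error bars are exact 95% Poisson intervals; regulatory T-like cells stand at 939 in wild type and at 387 and 389 in the deletion libraries.

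The deletion groups with and without alopecia share their genotype, so their comparison asks what differs in skin that has lost hair. Whatever else set these mice apart enters it as well. Among CD45-positive cells, macrophages were 6.93% (6.41 to 7.47) of cells with alopecia against 4.02% (3.37 to 4.76) without (1.72-fold, 1.42 to 2.10). Dermal gamma delta T cells were 13.4% against 10.1% (1.32-fold, 1.17 to 1.5) and regulatory T cells 8.78% against 6.87% (1.28-fold, 1.10 to 1.49). Called by marker UMIs of each cell, regulatory T cells were 9.26% and 8.94% (log2 ratio 0.05 in place of 0.35). After thinning to 1000 UMIs the marker rule gave 3.19% (2.83 to 3.59) and 2.75% (2.20 to 3.39), so that the size of this difference depends on how the cells are called. NK cells, few in number, were 0.667% against 0.309% (2.16-fold, 1.09 to 4.73). Type 2 conventional dendritic cells made up a smaller part with alopecia, 7.02% against 9.77% (0.718-fold, 0.626 to 0.825), and so did mast cells, 2.79% against 4.05% (0.689-fold, 0.555 to 0.858). CD8 T cells, the killer lymphocytes tied to alopecia areata, were scarce in both, 1.56% (1.31 to 1.84) with and 1.82% (1.39 to 2.35) without alopecia, a ratio of 0.855 (0.626 to 1.18), or 4.27% and 4.27% by marker UMIs of each cell. CD4 T cells were 6.37% and 5.69%, Langerhans cells 3.90% and 3.93%. Some classes left unnamed differed as well. Unnamed lymphoid A, whose best score was for NK cells, was 4.27% with alopecia against 8.44% without (0.506-fold, 0.432 to 0.593). In 91.5% and 94.5% of its cells 3 or more UMIs of T-cell receptor complex genes were found. Unnamed myeloid B was 4.93% against 2.845% (1.73-fold, 1.38 to 2.19). The no-alopecia library also held 7.82% fibroblasts within its CD45-positive sort, against 1.64% with alopecia. With at most 5% mitochondrial UMIs the log2 ratio for macrophages was 0.30 in place of 0.78.

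CD4 T cells of the alopecia library had more RNA of the type 17 cytokines than those of the no-alopecia library. Il17f (6.87-fold, 4.15 to 12.2) and Il17a (2.90-fold, 2.23 to 3.84) were higher than without alopecia, and Ifng, the main type 1 cytokine, stood at 306 against 152 CPM (log2 ratio 1.01, 0.72 to 1.30). The type 17 list had a median log2 ratio of 0.75 (0.28 to 1.60), with 4 of 7 members at least 1.5-fold higher and 0 lower, at percentile 100 of random lists. Against wild type its median was -1.06 (-1.57 to -0.78) without and -0.23 with alopecia, so that the alopecia library lay nearer to wild type. Fos (2.19-fold, 1.95 to 2.46), an early response gene, and Arhgap15 (1.98-fold, 1.72 to 2.27), a regulator of Rac, were also higher. Lower genes were Tnc (8.34-fold, 4.61 to 16), the matrix protein tenascin C, Idi1 (3.72-fold, 2.38 to 5.88), an enzyme of isoprenoid synthesis, Penk (3.58-fold, 2.28 to 5.68), the enkephalin precursor, and Ier5l (2.92-fold, 2.34 to 3.66). Interferon gamma response genes had a median of -0.22 (-0.40 to -0.01), with 6 of 20 lower and 1 higher, among them Tgtp2 at -2.27 and Igtp at -1.26. Cxcl10 was at -1.06 (-1.47 to -0.65). Inhibitory receptors had a median of -0.34 (-0.52 to -0.10), cytotoxic effectors -0.03 (-0.15 to 0.42) and dissociation stress genes 0.30 (0.22 to 0.39). The class joined a pair of clusters whose weights differed: lymphoid cluster 5 held 60.3% of the class with alopecia and 47.8% without, lymphoid cluster 6 held 39.7% and 52.2%. Red-cell RNA differed as well: the hemoglobin list had 7.75 (7 to 7.79), and Hbb-bs had 1617 counts with alopecia and 0 without, at least 215-fold higher against a floor of 3 counts per class sum. With each cell weighted alike, the log2 ratio of Penk was -0.99 in place of -1.84.

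Regulatory T cells of the alopecia library had lower interferon gamma response genes: the list median was -0.57 (-0.72 to -0.34), with 10 of 21 members lower and 0 higher, at percentile 0.0. Gbp6 (2.72-fold, 1.91 to 3.88) and Gbp5 (log2 ratio -1.41), both interferon-induced GTPases, were among them. Foxp3, the lineage factor of these cells, was at 640 against 886 CPM (-0.47, -0.59 to -0.34), and Gzmb at -0.48 (-0.65 to -0.30). Socs3 (2.40-fold, 2.02 to 2.85), a brake on cytokine signalling, Ly6a (2.57-fold, 2.04 to 3.25) and Cdk8 (2.12-fold, 2.07 to 2.16), a Mediator kinase, were lower. Cdk8 was lower in all 9 CD45-positive classes examined and so was not particular to regulatory T cells. Higher were Arhgap15 (2.47-fold, 2.14 to 2.87), Slc4a7 (3.39-fold, 1.99 to 6.19), a bicarbonate carrier, Mlec (3.22-fold, 1.98 to 5.56), a lectin of the endoplasmic reticulum, and Cxcl2 (2.06-fold, 1.64 to 2.60). The IL-2 and JAK-STAT pathway list had a median of -0.17 (-0.30 to -0.07), with 2 of 18 members lower. Genes of central memory and naive T cells had a median of 0.41 (0.01 to 0.54), dissociation stress genes 0.08 (0.01 to 0.19) and cytotoxic effectors 0.06 (-0.02 to 0.67). MHC class II genes had 0.67 (0.22 to 1.05), and free RNA from other cells can carry 5 of the 6 measured.

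Dermal gamma delta T cells with alopecia had less Cxcl10 (3.84-fold, 3.35 to 4.41), an interferon-induced chemokine, and more Jun (2.82-fold, 2.54 to 3.13), an early response gene. Their interferon gamma response list had a median of -0.29 (-0.42 to -0.03), with 8 of 20 members lower and 2 higher. Dissociation stress genes lay the other way, with a median of 0.38 (0.30 to 0.42) and 6 of 19 members higher. Dhx40 (3.28-fold, 2.42 to 4.54), an RNA helicase, Cxcl2 (2.39-fold, 2.04 to 2.81), which attracts neutrophils, and Hsph1 (2.28-fold, 1.98 to 2.64), a heat-shock protein, were higher. Lower were Ccr7 (2.48-fold, 1.93 to 3.19), the lymph node homing receptor, and Tinf2 (2.32-fold, 1.92 to 2.82), a telomere protein. Of 6 measured chemokines 4 were higher, with a median of 1.23 (0.54 to 1.72). Inhibitory receptors had a median of -0.41 (-0.55 to 0.04), and the IL-2 and JAK-STAT pathway -0.08 (-0.28 to -0.03). Here too the clusters differed in weight, with lymphoid cluster 4 at 49.8% of the class with alopecia and 27.7% without, and lymphoid cluster 2 at 31.6% and 54.0%.

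Antigen presentation genes of type 2 conventional dendritic cells differed little. The MHC class I list had a median of 0.09 (0.03 to 0.20) and the MHC class II list 0.03 (0.01 to 0.07), with 16 of 16 and 8 of 8 members within 1.5-fold. The interferon gamma response list stood at -0.09 (-0.23 to 0.05), the type I interferon list at 0.43 (-0.02 to 0.71), chemokines at 0.39 (0.21 to 0.52) and dissociation stress at 0.28 (0.20 to 0.33). Higher genes were Mucl1 (12.2-fold, 7.29 to 22.1), Lpl (3.14-fold, 2.18 to 4.64), lipoprotein lipase, Dhx40 (2.73-fold, 2.19 to 3.44) and Fkbp5 (2.66-fold, 2.18 to 3.28), a co-chaperone induced by glucocorticoids. Lower were Slc35f3 (3.47-fold, 2.63 to 4.59), Il1rapl1 (3.31-fold, 2.88 to 3.80) and Zc3h7a (2.45-fold, 2.34 to 2.56). T-cell receptor complex RNA was common in this class, with 3 or more such UMIs in 61.4% of its cells without and 62.8% with alopecia. Without those cells the log2 ratio of Il1rapl1 was -2.35 in place of -1.72, that of Dhx40 2.19 in place of 1.45 and that of Mucl1 2.58 in place of 3.61, which was 2.20 as a mean over cells and 2.71 with no more than 5% mitochondrial UMIs. Mucl1 and Lpl were also leading genes of unnamed myeloid B, whose share was 1.73-fold higher with alopecia. Slc35f3 was a leading gene of unnamed lymphoid A, whose share ratio was 0.506. Whether RNA of those clusters carries these differences was not tested. The MHC class II median turned to -0.02 under trimmed-mean scaling and to -0.07 with doublets kept. Macrophages had medians of 0.02 (-0.13 to 0.25) for interferon gamma response, 0.48 (-0.06 to 0.87) for type I interferon and 0.29 (-0.02 to 0.40) for cell death and hypoxia genes, with dissociation stress at -0.05.

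**Figure D2:**
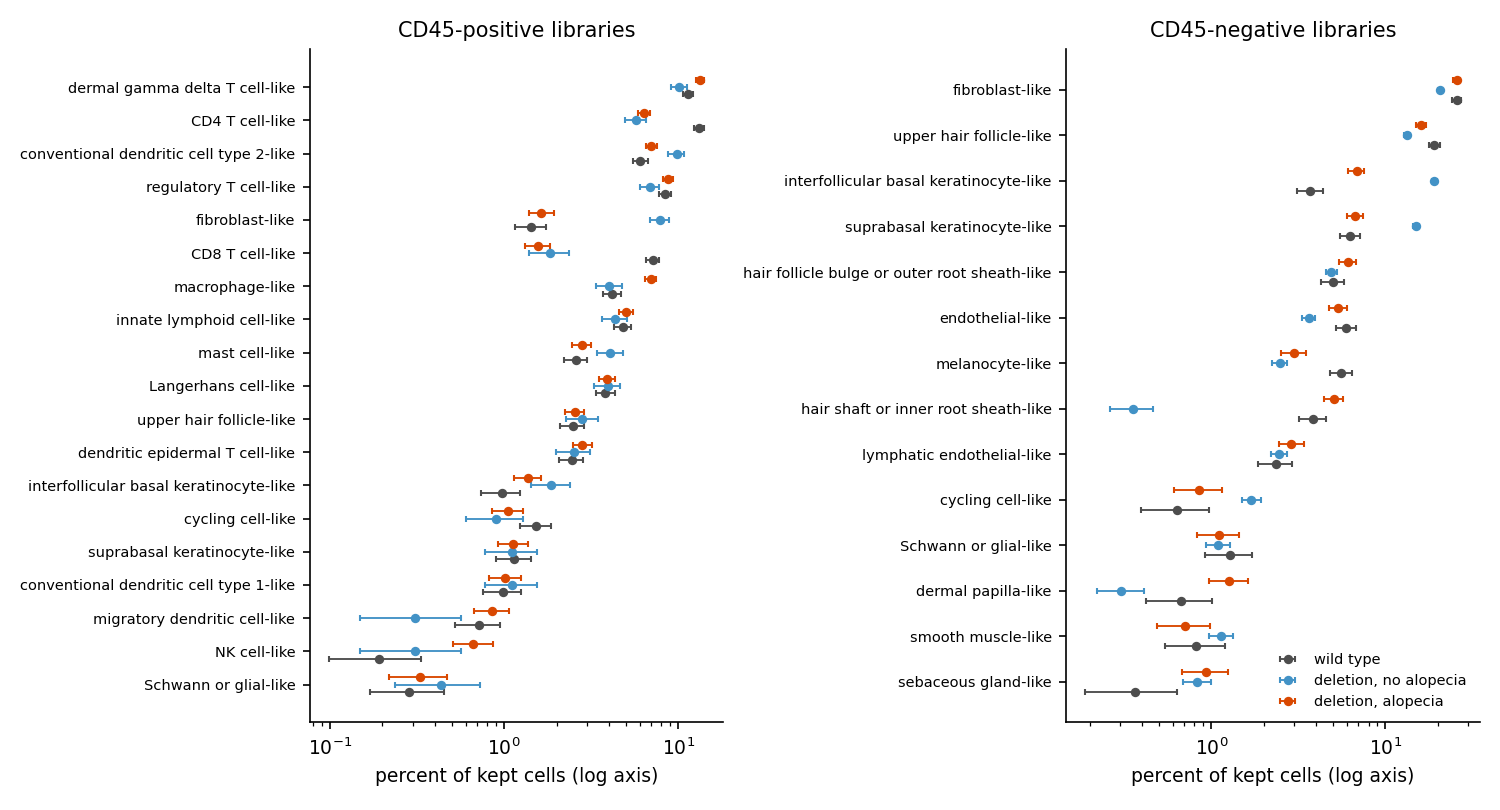
Percent of kept cells in each named class (x axis, logarithmic) in the 3 CD45-positive and the 3 CD45-negative libraries, for wild type, deletion without alopecia and deletion with alopecia. Unnamed classes are not drawn. Points are 1 library each and bars are exact 95% binomial intervals; hair shaft or inner root sheath-like cells stand at 0.353% without alopecia and 5.05% with it, CD8 T-like cells at 7.11% in wild type and 1.82% and 1.56% in the deletion libraries.

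In the CD45-negative sort the same comparison sets follicle, epidermis and stroma of the deletion libraries side by side. Hair shaft and inner root sheath cells, which a growing follicle makes, were 5.05% (4.44 to 5.70) of cells with alopecia against 0.353% (0.263 to 0.464) without (14.3-fold, 10.5 to 19.7). Dermal papilla cells, the signalling centre at the follicle base, were 1.27% against 0.305% (4.16-fold, 2.78 to 6.27). Interfollicular basal keratinocytes were a smaller part with alopecia, 6.83% (6.13 to 7.58) against 19.1% (18.4 to 19.7), and suprabasal keratinocytes as well, 6.69% against 15.1%. In wild type hair shaft, papilla, basal and suprabasal cells were 3.83%, 0.668%, 3.71% and 6.29%. The no-alopecia library thus lay further from wild type than the alopecia library in its hair shaft, basal and suprabasal shares. Fibroblasts were 25.6% against 20.6%, upper follicle cells 16.1% against 13.3%, and bulge or outer root sheath cells 6.06% against 4.89%. The cell filter removed 30.4% of barcodes with alopecia and 7.56% without, and 27.4% and 6.18% of barcodes were over the mitochondrial limit. In wild type 26.7% were removed and 22.3% were over the limit. Without the filter the hair shaft ratio was 3 in place of 3.84 on the log2 scale, the papilla ratio 1.46 in place of 2.06, and the ratios of fibroblasts (-0.04), upper follicle cells (-0.10) and bulge cells (-0.31) turned round. With 0.8% of cells removed as doublets per 1000 barcodes the papilla ratio was 3.49 and that of bulge cells 0.00.

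Upper follicle cells of the alopecia library had less RNA of the dissociation stress list, which holds many early response genes. It had a median of -1.03 (-1.05 to -0.98) with 15 of 20 members lower, and interferon gamma response genes had -0.37 (-0.62 to -0.11) with 5 of 16 lower. Cxcl10 (4.04-fold, 3.17 to 5.21), Ier3 (3.06-fold, 2.92 to 3.22), Gadd45b (2.95-fold, 2.72 to 3.20), a stress sensor, and Bhlhe40 (2.88-fold, 2.69 to 3.08), a transcriptional repressor, were lower. Fkbp5 (2.97-fold, 2.67 to 3.31) and Jarid2 (2.75-fold, 2.65 to 2.85), a Polycomb cofactor, were higher, and Il15, a cytokine for CD8 T and NK cells, was at 0.55 (0.29 to 0.81). Jarid2 was higher in all 8 CD45-negative classes examined and so was not particular to this one. The chemokine list had a median of -0.59 (-0.90 to -0.28), immune privilege genes -0.54 (-0.63 to -0.30) and cell cycle genes -0.95 (-1.68 to -0.60), though free RNA can carry 15 of the 19 cell cycle genes measured. Cluster 3 held 25.1% of this class with alopecia and 48.2% without, cluster 9 held 36.2% and 21.2%.

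Interfollicular basal cells with alopecia had more Tgm3 (9.23-fold, 7.64 to 11.2), a transglutaminase of the cornified envelope, Mir205hg (2.68-fold, 2.26 to 3.16), Glul (2.60-fold, 2.43 to 2.78), glutamine synthetase, and Tsc22d3 (2.35-fold, 2.22 to 2.5), which glucocorticoids induce. They had less Ch25h (2.71-fold, 2.47 to 2.99), an oxysterol enzyme and a leading gene of cluster 0, Slc27a3 (2.48-fold, 2.19 to 2.82), a fatty acid transporter, Gadd45b (2.12-fold, 1.94 to 2.31) and Cish (2.09-fold, 1.87 to 2.34), a target of STAT5. Cluster 0 held 52.3% of the class with alopecia and 66.8% without. Suprabasal cells had more Cstdc5 (38.6-fold, 30.2 to 49.8), a cystatin-like protease inhibitor, Glul (3.93-fold, 3.44 to 4.50), Slc15a2 (3.81-fold, 3.24 to 4.48), a peptide transporter, and Camk1d (2.97-fold, 2.92 to 3.02), a calcium-dependent kinase. Camk1d was higher in all 8 CD45-negative classes examined and so was not particular to suprabasal cells. Lower in suprabasal cells were Ch25h (6.06-fold, 4.64 to 8.05), Icam1 (2.95-fold, 2.52 to 3.48), the leukocyte adhesion molecule, and the NF-kB regulators Bcl3 (2.66-fold, 2.17 to 3.30) and Tnfaip3 (2.11-fold, 1.96 to 2.27). Keratinocyte stress genes had a median of -0.02 (-0.31 to 0.47) in basal and -0.33 (-0.67 to -0.19) in suprabasal cells, but the stefins Stfa3 and Stfa1 within the list were at 3.42 and 2.70 in basal and 3.61 and 2.95 in suprabasal cells. Chemokines had medians of -0.71 (-1.03 to -0.54) and -0.87 (-1.44 to -0.78), interferon gamma response -0.27 (-0.49 to -0.13) and -0.44 (-0.73 to -0.25), MHC class I -0.23 (-0.27 to -0.18) and -0.38 (-0.43 to -0.32), dissociation stress -0.39 (-0.41 to -0.36) and -0.58 (-0.61 to -0.55), in the same order. Clusters 4 and 5 held 35.7% and 55.9% of the suprabasal class with alopecia and 51.5% and 38.5% without. As a mean over cells, the log2 ratio of Cstdc5 was 4.05 in place of 5.27.

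Bulge and outer root sheath cells with alopecia had more RNA of the cell cycle: the list median was 1.45 (1.15 to 1.73), with 18 of 20 members higher, Cdk1 at 3.01 and Top2a at 2.01. Keratinocyte stress genes had 1.40 (1.10 to 1.62), with Sprr1a, a cornified envelope precursor, at 2.88. Immune privilege genes had -1.07 (-1.32 to -0.84), with Tgfb2 at -2.84 and Tgfb3 at -2.61, and MHC class I genes -0.41 (-0.64 to -0.35) with 7 of 16 lower. Interferon gamma response genes stood at 0.02 (-0.37 to 0.20) and dissociation stress genes at -1 (-1.03 to -0.93). These medians set unlike cells side by side, since cluster 20 held 69.9% of the class with alopecia and 8.1% without, and cluster 10 held 30.1% and 91.9%. The keratinocyte stress median was 0.60 with at most 5% mitochondrial UMIs and 0.32 with doublets kept.

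Fibroblasts with alopecia had more Mgp (9.04-fold, 7.78 to 10.6), an inhibitor of calcification, Pde1c (6.08-fold, 4.83 to 7.72), a phosphodiesterase, Mmp11 (4.81-fold, 4.07 to 5.70), a metalloproteinase that is a leading gene of cluster 13, and Lims2 (3.81-fold, 3.21 to 4.52). They had less Oxtr (4.95-fold, 3.83 to 6.49), the oxytocin receptor, Ly6c2 (2.74-fold, 2.52 to 2.98), Nrn1 (2.18-fold, 1.97 to 2.41) and Nr4a1 (2.11-fold, 2.01 to 2.21), an early response receptor. Clusters 1, 13 and 18 held 41.9%, 13.3% and 5.4% of the class with alopecia and 32.7%, 13.9% and 12.3% without. Collagen and matrix genes had a median of 0.18 (0.14 to 0.24), with 5 of 22 higher, among them Col14a1 at 1.82 and Postn at 1.22. MHC class I genes had -0.34 (-0.39 to -0.28), with 16 of 16 within 1.5-fold, dissociation stress -0.49 (-0.57 to -0.46), interferon gamma response 0.06 (-0.19 to 0.11) and dermal papilla genes -0.08 (-0.19 to 0.10). As means over cells, Mgp was at 2.58 in place of 3.18 and Mmp11 at 1.43 in place of 2.27 on the log2 scale. Endothelial cells with alopecia had lower interferon gamma response genes, -0.75 (-0.82 to -0.53) with 14 of 25 lower, Cxcl9 at -1.64 and Cd274, the ligand of PD-1, at -1.38. Endothelial activation genes had -0.44 (-0.94 to -0.23), with the cytokine gene Csf3 at -4.32 and Lrg1 at 2.03, MHC class I -0.19 (-0.25 to -0.09), dissociation stress -0.58 (-0.68 to -0.53) and chemokines -1.22 (-1.63 to -0.77), or -0.35 without members that free RNA can carry. Outside this class lay an unnamed endothelial-type cluster, with Selp, Sele, Csf3, Ackr1 and Lrg1 of the activation list among its leading genes. It was 0.747% of cells with and 1.16% without alopecia, and whether its RNA carries the activation median was not tested. Melanocytes had lower interferon gamma response genes, -0.98 (-1.49 to -0.84) with 13 of 15 lower, and lower MHC class I genes, -0.79 (-0.98 to -0.64) with 11 of 14, and their dissociation stress genes had -0.95. Their cell cycle genes had 2.15 (1.06 to 2.79), with Mki67 at 3.96 (2.31 to 6.30), but 0.58 when each cell was weighted alike.

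**Figure D3:**
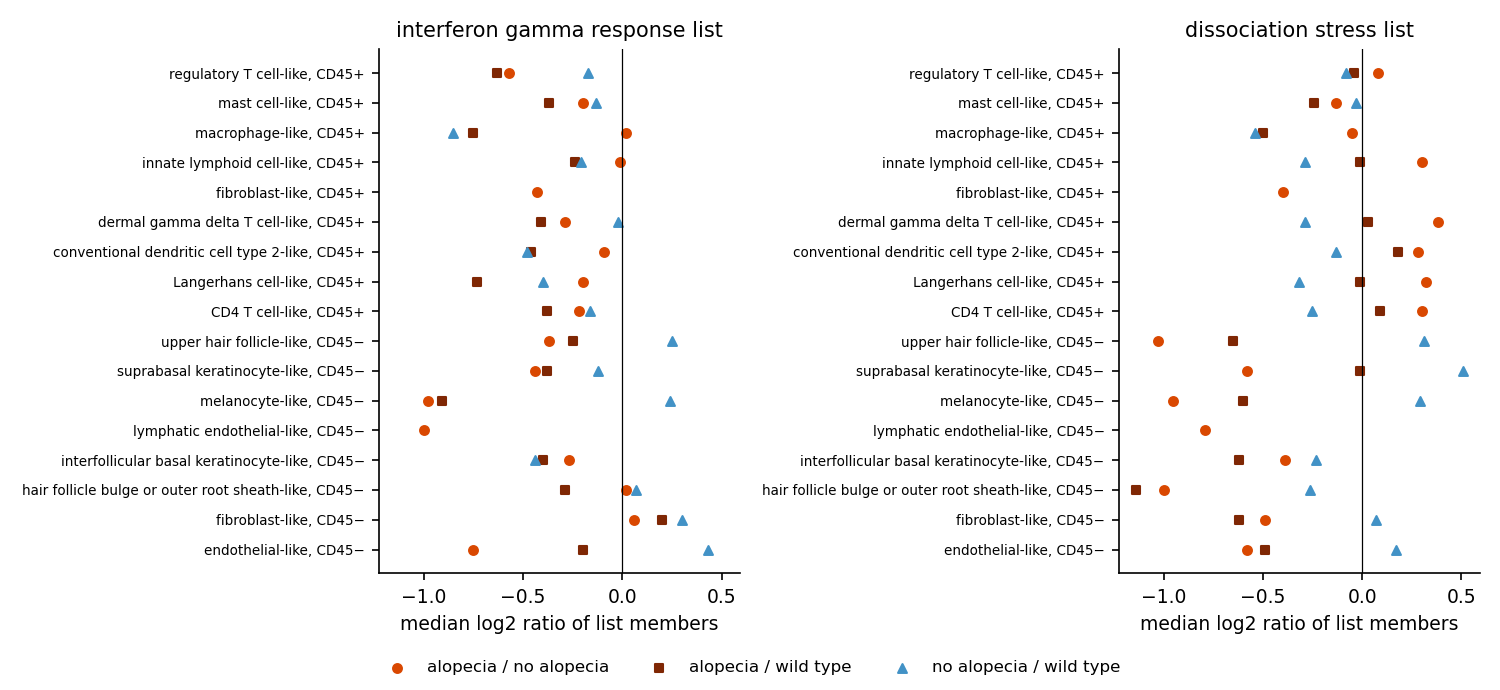
Median log2 ratio of the members of the interferon gamma response list (left) and of the dissociation stress list (right) in each named cell class, for alopecia against no alopecia, alopecia against wild type and no alopecia against wild type. Each point is 1 pair of libraries with no interval drawn; with alopecia against no alopecia the interferon median is -0.57 in regulatory T cells and the stress median is 0.38 in dermal gamma delta T cells and -1.03 in upper follicle cells.

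Set against wild type, the alopecia library differs by the enhancer deletion together with hair loss, and by whatever else set these mice apart. CD8 T cells were 1.56% of CD45-positive cells against 7.11% (6.49 to 7.77) in wild type, a ratio of 0.219 (0.180 to 0.266), and CD4 T cells 6.37% against 13.2%, a ratio of 0.484 (0.434 to 0.539) (8.63% and 13.2% by marker UMIs of each cell). The marker rule for CD4 T cells also takes in regulatory T cells with a Cd4 UMI, which the cluster class leaves out. After thinning to 1000 UMIs it gave 2.05% against 3.49%. Macrophages were 6.93% against 4.18% (1.66-fold, 1.43 to 1.92), NK cells 0.667% against 0.190% (3.51-fold, 1.87 to 7.17), and regulatory T cells 8.78% against 8.40%. CD8 T cells had less cytotoxic effector RNA, with a list median of -0.50 (-0.68 to -0.28) and 8 of 18 members lower, among them the granzymes Gzmb at -2.54 and Gzma at -2.39. Their inhibitory receptors had 0.15 (-0.16 to 0.24) and tissue residency genes -0.22 (-0.38 to -0.11). Called by marker UMIs of each cell in place of clusters, the CD8 share had a log2 ratio of -1.42, against -2.19 by clusters.

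Interferon gamma response genes were lower than wild type in the alopecia library's regulatory T cells (-0.63, -0.78 to -0.43, 13 of 23 lower), CD4 T cells (-0.38, -0.53 to -0.21) and gamma delta T cells (-0.41, -0.56 to -0.18). In macrophages the list had -0.75 (-0.93 to -0.64) with 16 of 25 lower, Cxcl9 at -2.96 and Cxcl10 at -2.84, chemokines had -1.48 (-1.62 to -1.40) and type I interferon genes -0.66 (-1.03 to -0.25), or -3.07 with only members of at least 100 counts. Dissociation stress genes of macrophages, a sign of handling, were lower than wild type as well, with medians of -0.50 with and -0.54 without alopecia. Type 2 dendritic cells had -0.46 (-0.66 to -0.39) for interferon gamma response, -0.83 (-0.97 to -0.52) for chemokines, -0.25 (-0.34 to -0.14) for MHC class I and 0.36 (0.30 to 0.38) for MHC class II. Ly6a, the surface marker Sca-1, was lower in CD4 T cells (32.3-fold, 20.3 to 54.7) and regulatory T cells (6.90-fold, 5.84 to 8.19). Ly6e was lower in CD4 T (8.60-fold, 7.53 to 9.87), gamma delta T (21-fold, 19.1 to 23.1), regulatory T (9.89-fold, 9.01 to 10.9) and dendritic cells (9.52-fold, 8.42 to 10.8). Apobec3, an antiviral deaminase, was lower in gamma delta T cells (11.9-fold, 7.92 to 18.4) and Oasl1 in dendritic cells (20.4-fold, 11.1 to 41.7). Higher were Ehd3 in CD4 T (2.52-fold, 2.09 to 3.05) and gamma delta T cells (3.52-fold, 2.90 to 4.31), and the protease gene Ctse in dendritic (3.83-fold, 2.66 to 5.66), gamma delta T (2.69-fold, 2.14 to 3.41) and regulatory T cells (2.65-fold, 1.90 to 3.74). Ifnar2, a type I interferon receptor chain, was higher in regulatory T cells (2.92-fold, 2.35 to 3.65), Apbb2 in CD4 T cells (2.10-fold, 1.61 to 2.74) and Slc15a2 in dendritic cells (2.33-fold, 1.84 to 2.96). The IL-2 and JAK-STAT pathway list had -0.29 (-0.34 to -0.18) in regulatory and -0.27 (-0.32 to -0.19) in gamma delta T cells, and type 17 genes -0.23 (-0.41 to 0.00) in CD4 T cells, where Il22, a leading gene of lymphoid cluster 6, was at -3.55 and that cluster held 39.7% of the class against 51.7% in wild type. MHC class II genes of macrophages had 0.44 (0.42 to 0.56), but -0.16 without cells holding T-cell receptor complex RNA. Without such cells the macrophage medians were -1.56 for type I interferon and -2.14 for chemokines, the dendritic interferon gamma median turned to 0.10, and Oasl1 in dendritic cells was at -3.68 in place of -4.35. The type 17 median was 0.03 with each cell weighted alike.

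Among CD45-negative cells, hair shaft and inner root sheath cells were 5.05% with alopecia and 3.83% (3.20 to 4.54) in wild type (1.32-fold, 1.06 to 1.65), and melanocytes 2.97% and 5.59% (0.531-fold, 0.424 to 0.665). Ly6c2 was higher in fibroblasts (242-fold, 66.7 to 2000, from 2 counts in wild type) and endothelial cells (78.0-fold, 33.2 to 241). Fibroblasts also had more Mmp11 (7.34-fold, 5.45 to 10.1) and less Tgm2 (8.10-fold, 6.07 to 11), a tissue transglutaminase, and Plac9b (3.44-fold, 3 to 3.94). In endothelial cells Esm1 (5.37-fold, 2.65 to 12.3) was higher, and Mt2 (4.32-fold, 3.67 to 5.10), a metallothionein, and Apobec3 (5.01-fold, 3.21 to 8.11) were lower. Suprabasal cells had less Cdsn (167-fold, 45.8 to 1391, from 2 counts with alopecia), the adhesion protein corneodesmosin, and Ifitm6 (21.2-fold, 12.6 to 38.7), and more Adm (2.97-fold, 2.15 to 4.17), the precursor of adrenomedullin, and Pxdc1 (2.94-fold, 2.17 to 4.06), but the make-up of the class differed: clusters 4, 5 and 22 held 35.7%, 55.9% and 8.4% of it with alopecia and 22.2%, 56.0% and 21.7% in wild type. Upper follicle cells had more Eya2 (2.23-fold, 1.78 to 2.82) and Fmo5 (2.20-fold, 1.91 to 2.54) and less Ly6e (3.49-fold, 3.05 to 4.01) and Chit1 (3.14-fold, 2.5 to 3.96), a chitinase. In fibroblasts MHC class I had 0.16 (0.10 to 0.24), collagen and matrix 0.04 (-0.02 to 0.09), interferon gamma response 0.20 (0.01 to 0.31) and dissociation stress -0.62 (-0.66 to -0.59), with 13 of 20 members lower. Elsewhere MHC class I had -0.32 (-0.46 to -0.17) in suprabasal cells, interferon gamma response -0.25 (-0.42 to -0.03) in upper follicle and -0.20 (-0.39 to -0.02) in endothelial cells, dissociation stress -0.65 (-0.69 to -0.62) in upper follicle cells, and cell cycle 0.18 (-0.05 to 0.50) in bulge cells and 2.76 (1.83 to 3.13) in melanocytes. Dissociation stress was at -1.14 in bulge cells, -0.60 in melanocytes and -0.49 in endothelial cells. The make-up of other classes differed as well: cluster 20 held 69.9% of bulge cells against 43.9% in wild type, cluster 3 held 25.1% against 38.2% of upper follicle cells, and cluster 1 held 41.9% against 32.7% of fibroblasts. Red-cell RNA in wild-type endothelial cells set the hemoglobin list apart, at -8.15 (-9.03 to -7.39), with Hbb-bs at 11 counts with alopecia against 2513. With doublets kept that median was -1.64, and as a mean over cells -7.12. As means over cells, the log2 ratios were 6.87 in place of 7.92 for Ly6c2 in fibroblasts, -5.74 in place of -7.39 for Cdsn, -3.48 in place of -4.41 for Ifitm6 and 0.77 in place of 2.76 for the melanocyte cell cycle median.

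The library without alopecia, set against wild type, compares deletion and wild type in skin that kept its hair, and other differences between these mice enter here as well. CD8 T cells were 1.82% against 7.11% (ratio 0.257, 0.192 to 0.337) and CD4 T cells 5.69% against 13.2% (ratio 0.432, 0.366 to 0.508), or by marker UMIs of each cell 4.27% against 11.4% and 9.15% against 13.2%, while regulatory T cells were 6.87% against 8.40% (ratio 0.818, 0.696 to 0.958). Here too the marker rule for CD4 T cells takes in regulatory T cells with a Cd4 UMI, and after thinning it gave 1.77% against 3.49%. CD4 T cells had lower type 17 genes, with a median of -1.06 (-1.57 to -0.78) and 7 of 9 lower, Il17f at -3.01 and Il22 at 0 counts against 59.5 CPM, at least 15.6-fold lower against the floor of 3 counts. Ly6a (33.2-fold, 16 to 82.7) was lower there, and Ccl4 (4.23-fold, 2.99 to 5.97), a chemokine, and Penk (4-fold, 2.67 to 5.96) were higher. With doublets kept the log2 ratio of Ly6a was -7.96 in place of -5.05, and with no more than 5% mitochondrial UMIs that of Ccl4 was 2.87 in place of 2.08. Ly6e was again lower in dendritic (12-fold, 10.1 to 14.4), gamma delta T (19.1-fold, 16.5 to 22.3) and regulatory T cells (10.2-fold, 8.65 to 12), with Oasl1 (10.6-fold, 5.90 to 21) in dendritic, Dhx40 (9.50-fold, 7.06 to 13.1) in gamma delta T and Apobec3 (9.55-fold, 4.75 to 22.5) in regulatory T cells. Higher were Ehd3 in gamma delta T (4.49-fold, 3.62 to 5.59) and dendritic cells (2.99-fold, 2.22 to 4.07), Tnfsf8, the CD30 ligand, in gamma delta T cells (3.30-fold, 2.60 to 4.20), and Ifnar2 (3.14-fold, 2.42 to 4.09) and Cdk8 (2.02-fold, 1.97 to 2.06) in regulatory T cells. Foxp3 in regulatory T cells was at 0.36 (0.23 to 0.49). Of gamma delta T cells lymphoid cluster 8 held 18.3% against 31.9% in wild type. Interferon gamma response genes had -0.85 (-1.04 to -0.59) in macrophages with 17 of 25 lower, -0.48 (-0.63 to -0.35) in dendritic cells, -0.17 (-0.27 to -0.01) in regulatory T, -0.16 (-0.29 to 0.07) in CD4 T and -0.02 (-0.18 to 0.15) in gamma delta T cells. Type I interferon genes had -1.67 (-2.04 to -0.93) in macrophages and -0.83 (-1.61 to -0.57) in dendritic cells, chemokines -1.65 (-1.76 to -1.40) and -0.88 (-1.10 to -0.75), and MHC class II genes 0.37 (0.32 to 0.42) and 0.28 (0.22 to 0.33). In regulatory T cells the IL-2 and JAK-STAT pathway list stood at 0.00 (-0.11 to 0.08) and cytotoxic effectors at -0.98 (-1.18 to -0.34), or -0.33 without members that free RNA can carry, -0.30 at no more than 5% mitochondrial UMIs and -0.08 with only members of at least 100 counts. Without cells holding T-cell receptor complex RNA the macrophage chemokine median was -0.63, and Oasl1 in dendritic cells was at -5.26 in place of -3.41. As means over cells, Penk stood at 1.09 in place of 2.00.

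The CD45-negative cells without alopecia held few hair shaft and inner root sheath cells, 0.353% against 3.83% in wild type (ratio 0.0923, 0.0653 to 0.129), and many interfollicular basal keratinocytes, 19.1% against 3.71% (5.15-fold, 4.29 to 6.22). Endothelial cells had higher activation genes, with a median of 1.64 (0.97 to 1.86) and 7 of 10 higher, among them Vcam1, a leukocyte adhesion molecule, at 4.04 (1.47 to 9.39). Their chemokines had 1.10 (0.35 to 1.55), with Cxcl9 at 2.33 (0.66 to 4.68), their interferon gamma response genes 0.43 (0.31 to 0.56) with 7 of 25 higher, and their hemoglobin genes -8.62 (-9.27 to -7.95). Higher as well were Ly6c2 (138-fold, 58.9 to 425) and Bmp2 (5.88-fold, 3.64 to 10.1), a bone morphogenetic protein, while Lpl (16.4-fold, 8.93 to 32.9) and Apobec3 (9.19-fold, 5.84 to 15) were lower. The unnamed endothelial-type cluster, led by several activation genes and outside this class, was 1.16% against 0.547% in wild type. Whether its RNA carries the activation median was not tested. Fibroblasts had more Ly6c2 (662-fold, 183 to 5470, from 2 counts in wild type) and Ncam2 (3.38-fold, 2.83 to 4.07), an adhesion molecule, and less Plac9b (9.94-fold, 8.48 to 11.7) and Col14a1 (6.41-fold, 5.30 to 7.78), a fibril-associated collagen. Their MHC class I genes had 0.50 (0.41 to 0.55) with 5 of 16 higher, their collagen and matrix genes -0.26 (-0.30 to -0.21) with 5 of 22 lower. Suprabasal cells had less Cstdc5 (15.5-fold, 11.6 to 20.9) and Cdsn (12.2-fold, 9.85 to 15.2) and more Pxdc1 (4.82-fold, 3.66 to 6.5) and Ifnar2 (3.97-fold, 2.90 to 5.57), with 51.5%, 38.5% and 9.9% of the class in clusters 4, 5 and 22 against 22.2%, 56.0% and 21.7% in wild type. Upper follicle cells had less Fkbp5 (3.92-fold, 3.53 to 4.36) and more Thbs1 (3.20-fold, 2.81 to 3.66), a matrix glycoprotein, and Krt5 (2.15-fold, 2.08 to 2.22), the basal keratin, with medians of 0.59 (0.39 to 0.81) for chemokines and 0.65 (0.32 to 1.25) for the cell cycle, while cluster 3 held 48.2% of this class against 38.2% in wild type and cluster 9 held 21.2% against 29.1%. Dissociation stress was at 0.31 in upper follicle, 0.51 in suprabasal and -0.26 in bulge cells, 0.17 in endothelial cells and 0.07 in fibroblasts. Bulge cells had lower cell cycle (-1.11, -1.38 to -0.69) and keratinocyte stress genes (-0.91, -1.49 to -0.74), with cluster 20 at 8.1% of the class against 43.9% in wild type. With only members of at least 100 counts the medians were 0.65 for endothelial activation, 0.11 for endothelial chemokines, -0.22 for the bulge cell cycle and -1.55 for bulge stress genes. Without members that free RNA can carry, endothelial activation had 0.95 and bulge stress genes -1.55. With doublets kept, the endothelial interferon gamma median was -0.02 and Thbs1 stood at 2.75 in place of 1.68, or 2.85 with no more than 5% mitochondrial UMIs. As means over cells, endothelial activation had 0.97, endothelial hemoglobin -7.00 and endothelial Cxcl9 0.90 in place of 2.33. In the same way Ly6c2 in fibroblasts was at 8.31 in place of 9.37, Cstdc5 at -2.75 in place of -3.96, Cdsn at -2.97 in place of -3.61, Col14a1 at -2.01 in place of -2.68 and Pxdc1 at 2.88 in place of 2.27 on the log2 scale.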

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

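Except those on time of day and on hair shaft cells without the cell filter, the tests in this part were chosen after the results were seen. The test on exchanged labels was added last, its bound set before its own value was seen, and the genes examined first (among them Cdk8, Camk1d, Jarid2, Cmss1 and Gm42418) were picked after their values had been seen.

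Jarid2, a Polycomb cofactor, lay in opposite directions in the sorts when alopecia was set against no alopecia. Its median log2 ratio was -0.23 over 9 CD45-positive classes, lower in all 9, and 1.25 over 8 CD45-negative classes, higher in all 8. Cmss1 had -0.33, lower in 9 of 9, against 0.41, higher in 8 of 8. Opposite directions in every class singled these genes out, and the difference between the sorts was not tested. Cdk8, Camk1d and Gm42418 were not opposite in every class, with medians of -0.76 and 0.04, -0.13 and 1.44, and -0.12 and 0.57, though Camk1d was lower in 6 and Gm42418 in 7 of 9 CD45-positive classes and both were higher in all 8 CD45-negative ones. A class of 1 library shares its preparation with all other classes of it, so that 9 classes are not 9 independent samples.

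A set of 21 genes differed from wild type the same way in both deletion groups in at least 50% of the classes that measured them, and the other way in none, 18 lower and 3 higher, out of 4632 examined over 15 classes. Ly6a (median log2 ratio -3.73, 11 of 12 classes), Apobec3 (-2.94, 8 of 8) and Ly6e (-2.61, 10 of 14), which all lie on chromosome 15, led the lower genes, Ehd3 (1.54, 5 of 5) was higher, and Il2ra itself was among them (-1.01, 4 of 8). Genes that free RNA can carry were not left out of this set, which also held Gzmb, Ifng, Ccl4 and Ccl5. Whether RNA of other cells carries any of these differences was not tested. One differing segment behind the whole set is argued against, since the fullest chromosome, number 11, held 19% of the genes against a 95th percentile of 23.8% in random sets. This share cannot tell whether a segment carries part of the set. Ly6a, Ly6e and Apobec3 lie within 4.94 Mb of each other, and a segment holding them stays open. Depth or scaling is argued against by a largest median of all genes of 0.08 over these classes. Weaker interferon signalling stays open: the lower genes had a median of -1.34, and the type I interferon list had -0.17 over values from -1.67 to 0.70, of which 7 of 24 lay above 0, while in macrophages the interferon gamma list was lower too (-0.85 without and -0.75 with alopecia). A genetic background that differs at several loci may explain part of the set and stays open: 6 pairs of the genes lay within 10 Mb of each other, as many as in 223 of 10000 random sets, but neighbours of 1 gene family count among the pairs, and this test followed the one on a single segment, when the chromosome 15 genes were known. An effect of the enhancer deletion itself was not tested and stays open as well.

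Glucocorticoid-responsive genes, in a list written after Fkbp5, Tsc22d3, Zbtb16 and Glul had been seen, had medians above 0 for alopecia against no alopecia in 16 of 17 classes, of which 3 reached 1.5-fold (medians from -0.05 to 0.71). Fkbp5 was higher in all 17, with a median log2 ratio of 1.54, and without alopecia it was lower than wild type in all 15 classes measured, with -1.40. Tsc22d3 did not follow it there, higher than wild type in 8 and lower in 7 of 15 classes (median 0.10), while Zbtb16 was lower in 11 and higher in 2 of 14 (median -0.97). With alopecia against wild type the medians were 0.19 for Fkbp5, 0.56 for Tsc22d3 and 0.07 for Zbtb16. For time of day at collection, evening and morning clock genes lay in opposite directions with a log2 gap of at least 0.58 in 5.88% of classes (1 of 17). This argues against a shift in time large enough to part the clock lists by that gap. Evening and morning signs were opposite, at any gap, in 7 classes, with evening genes the higher ones in 2. The test cannot decide on a smaller shift, since the glucocorticoid medians reached 1.5-fold, the same size, in only 3 of 17 classes. Stress during dissociation is argued against in the CD45-negative sort, where its genes went the same way in 12.5% of classes (1 of 8). In the CD45-positive sort it stays open, as they went the same way in 66.7% (6 of 9). Both counts come from 1 pair of libraries per sort, whose classes are not independent. Stress of the animals before collection, or a biological difference in steroid exposure with hair loss, could give the pattern, and neither was tested.

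Hair shaft and inner root sheath cells were more frequent in the alopecia than in the no-alopecia library. Wild type, at 3.83%, lay nearer to the alopecia library. Loss of cells to the filter is argued against by a log2 ratio of 3 (2.60 to 3.41) without any filter, and dilution by interfollicular epidermis by 3.23 (2.79 to 3.70) among follicle keratinocytes alone. Labels exchanged in the CD45-negative sort alone would turn this difference round. An exchange in 1 sort is argued against by classes found in both sorts (at least 30 cells per library), where log2 ratios of genes, alopecia over no alopecia, had a median Spearman correlation of 0.24 between the sorts (0.15 to 0.29 over 4 classes), since an exchange needs a negative one. It takes the sorts of a group to be from the same mice, and an exchange in both sorts was not tested. Follicles in different phases of the hair cycle may explain it: dermal papilla cells per fibroblast had a log2 ratio of 1.74 (1.16 to 2.33), and the 9 pigment genes of melanocytes a median of 0.82 (0.72 to 0.91). With 1 library per group this cannot be parted from where on the body, and from which mice, the skin was taken.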

How the results depend on the processing

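Settings added after the data were seen were shares among leukocyte classes or follicle keratinocytes or outside keratinocytes, and classes without cells holding T-cell receptor complex RNA. No replicate could be left out, as each group had 1 library. Of 1327 alternative values for 262 gene ratios, 1224 stayed within the counting interval, 98 lay outside it and 5 reversed. For 112 list medians these were 618, 115 and 6 of 739, for 34 shares 184, 23 and 4 of 211. A value counts as reversed only where the planned interval lay away from no change. Other changes of sign are counted as within or outside the interval. The log2 values below are of alopecia against no alopecia unless said otherwise, and the cause was not tested for any. Without the cell filter shares had ratios of -0.04 for fibroblasts, -0.31 for bulge, -0.10 for upper follicle, 3 for hair shaft and -1.86 for basal cells (planned: 0.32, 0.31, 0.27, 3.84, -1.48). With 0.8% doublets bulge cells had 0.00 and basal cells -1.22, with seed 1 basal cells -1.26, and among follicle keratinocytes hair shaft cells 3.23. At most 5% mitochondrial UMIs gave macrophages 0.30, and marker UMIs gave regulatory T cells 0.05 and CD8 T cells against wild type -1.42, or -1.50 thinned. As means over cells, Cxcl10 in dendritic cells had 0.40, the interferon gamma list in regulatory T cells -0.34 and type 17 genes of CD4 T cells with alopecia against wild type 0.03. Without cells holding T-cell receptor complex RNA, dendritic cells had 0.36 for Cxcl10 and 0.00 for Foxp3, and with alopecia against wild type 0.10 for the interferon gamma list, and macrophages -0.16 for MHC class II with alopecia against wild type. With doublets kept, gamma delta T cells had -0.42 for Ifng with and -0.13 for Gzmb without alopecia against wild type, MHC class II of dendritic cells -0.07 (-0.02 under trimmed-mean scaling) and the interferon gamma list of endothelial cells without alopecia against wild type -0.02. Members of at least 100 counts gave the bulge cell cycle 1.02.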

Other observations

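Migratory dendritic cells, on their way from skin to lymph node, were 0.847% of CD45-positive cells with alopecia, 0.309% without and 0.713% in wild type, a ratio of 2.74 (1.41 to 5.95) between the deletion libraries. Smooth muscle cells were 0.706%, 1.14% and 0.820% of CD45-negative cells in the same order, a ratio of 0.618 (0.414 to 0.898) between the deletion libraries. For the 4 classes that follow the interval of that ratio held 1. Type 1 conventional dendritic cells, which present antigen to CD8 T cells, were 1.02%, 1.11% and 0.982%, dendritic epidermal T cells 2.81%, 2.51% and 2.44%, lymphatic endothelial cells 2.89%, 2.44% and 2.34%, and sebaceous gland cells 0.934%, 0.831% and 0.364%. Without the cell filter the log2 ratio of sebaceous gland cells between the deletion libraries was -0.62 in place of 0.17. These classes were chosen after their shares had been seen.

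T-cell receptor complex RNA was found in myeloid classes of every group. The percent of cells with 3 or more such UMIs was 68.2% in wild-type macrophages, 53.8% without and 45.0% with alopecia, and 68.5%, 63.8% and 53.9% in Langerhans cells. Wild-type macrophages with it had a median depth of 7377 UMIs and those without it 2288.5. In unnamed myeloid clusters, in the order of wild type, no alopecia and alopecia, the percent was 15.2%, 12.2% and 13.3% (A) and 7.55%, 8.7% and 8.26% (B), and in fibroblasts of the same sort 2.22%, 0.791% and 2.07%. Free RNA, which reaches all classes of a library, is argued against as the whole cause by a test chosen after these values were seen: among cells of 2000 to 5000 UMIs it was 53.5%, 38.8% and 35.6% of macrophages and 4.55%, 0.0% and 2.63% of fibroblasts. Whether joined cells carry it was not tested.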
